A study of Mus musculus with 8 samples.

How the data were processed

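Whole intervertebral discs (lumbar levels 1 to 6 and tail levels 5 to 9) of Tagln-CreERt2; R26tdTomato mice were digested in 5 ml of 0.25% dispase with 0.25% type II collagenase for 1 hour, passed through a 40 micrometre strainer and profiled with droplet-based single-cell RNA sequencing at P10 and 8 weeks. GEO lists 8 samples, 4 per age. Per the file headers, the authors produced the matrices with Cell Ranger 3.1.0, and per the labels the genome build was mm10; Seurat 3 is named there without a stated role. The deposited matrices hold raw UMI counts, 1 gene matrix and 1 matrix of exogenous sequences per age. The deposited barcode and feature lists hold other content, namely the text names of the cells and of the genes or sequences. Every value is a whole number, and the barcodes of an age carry 1 suffix, so the 4 samples of an age could not be told apart and each age was treated as 1 library. The gene matrices hold 31053 genes and the barcodes the authors called as cells. The exogenous matrices hold 96 sequences (CRE, EGFP, TDT, WPRE4 and 92 ERCC spike-ins) over all whitelist barcodes and were joined to the cells by barcode. Gene positions came from GENCODE for the same build.

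Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which left 6999 of 7690 barcodes at P10 and 6481 of 7597 at 8 weeks. Doublets were scored per library with Scrublet as run in Scanpy, with an expected rate of 6%. At 8 weeks its threshold of 0.27 removed 131 cells (2.02%). At P10 its threshold was set at 0.626 and called 0 cells, so doublet calling has not worked there; a score limit of 0.25 in both libraries was added as an alternative. Both libraries were clustered together without batch correction, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at a resolution of 1, which gave 26 clusters. Tagln, hemoglobin, mitochondrial, Xist and Y-linked genes were left out of the variable genes. Clusters were named from fixed marker lists of 19 classes. A name needed at least 3 markers at a level 2-fold above the other cells and in at least 25% of the cluster, with a separate rule for chondrocytes (8 markers in 50% of cells) and a check against the 10 leading genes of the cluster. Of the classes, 11 were found. Names are written as "-like" because they rest on markers alone.

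Levels are summed UMIs of a class per 1000000 gene UMIs of the same cells (CPM). Ratios are those of CPM of summed counts, on the log2 scale, with exact conditional binomial intervals. A share of 0 is given with the limit that 3 counts allow, and a fold against 0 UMIs is computed against 3 counts over the group. Because cells of 1 library are not replicates, no p-value, standard error or count of changed genes over all genes was computed from cells. Intervals cover counting error alone. Counts of list members or named genes with an interval clear of 0 describe the pooled cells and are not tests. Genes entered a contrast with at least 100 UMIs in both sums together, or at least 50 in the splits of NP-like cells. Without cells carrying markers of another class, list medians in the report use the genes that passed with all cells, while the alternatives apply the minimum anew. Thinned shares come from a binomial draw of each cell down to 2000 UMIs with a fixed seed of 7; shallower cells were left out.

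Cell filters, clustering, markers, gene lists, contrasts, the TDT readout, the main scaling and the rule for naming genes were set before the data were examined. The rule names, in each contrast, the 8 highest and 8 lowest genes in NP-like cells, or 4 and 4 in another class, by the interval bound nearer to a ratio of 1, without mitochondrial, ribosomal, hemoglobin, Xist, Tsix, Y-linked and predicted genes. It adds up to 4 members of each list with the most UMIs, and always Tagln, tdTomato, Acta2 and the NP markers. The 18 lists cover notochord and hedgehog, epithelial-type keratins and junctions, cartilage and NP matrix, fibrillar and fibrous matrix, basement membrane, contractile and serum response factor targets, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, progenitor markers, TGF-beta and BMP, YAP and TEAD targets, matrix proteases and inhibitors, immediate early and heat shock genes, endoplasmic reticulum stress, interferon response, aging and cell cycle arrest, and ambient blood. A list with at least 3 measured members is given by its median log2 ratio and its percentile among 10000 random lists of the same size, matched on expression in 25 bins. The interval of a median is exact, from order statistics over the members, or their range with under 6 members. Genes were ranked and lists compared within contrasts of ages for classes with at least 100 cells at both ages.

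WPRE4 as a readout, its threshold of 10 UMIs, and the definition of cells with markers of another class were set after the data were seen. That definition asks for at least 10 UMIs summed over markers of 1 other class that have a median of 0 in NP-like cells at both ages. It was first tried with chondrocyte markers alone and then extended to all other classes. The background for the subtraction of free RNA is the mean per neutrophil-like or macrophage-like cell of the same library, the lower of the 2. It first left out blood cells with chondrocyte markers alone and was then redefined to leave out blood cells with markers of any class outside the blood, after a result with the first version had been seen; results with both are given. For the splits of NP-like cells, the genes and lists carried through all alternatives were chosen after a wider set had been run, and counts over the wider set are given as well. TDT per UMI in cells above and below the WPRE4 threshold, and depth and Tagln per NP-like cluster, were also computed after the data were seen.

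The alternatives were looser (200 genes, 25% mitochondrial) and stricter (1000 genes, 10%) cell filters, doublets kept, a doublet score under 0.25, resolutions of 0.5 and 2, each library clustered on its own, TMM and median-of-ratios scaling, totals without mitochondrial, ribosomal and hemoglobin UMIs, the mean of per-cell values, a gene minimum of 20 UMIs, thinning to 2000 UMIs, other TDT and WPRE4 thresholds and thinning depths, subtraction of the level in blood cells, NP-like cells without the cycling cluster or from cluster 14 alone, and NP-like cells without markers of another class, at both ages or at 1 age alone.

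The ratio, interval and list steps were tested on simulated data: with sums drawn for 11312 genes at the depth of the NP-like contrast, 95.7% of the intervals of unchanged genes held the true value. Of 200 random lists of 10 genes, 6.50% fell under percentile 5 and 4.50% over percentile 95. The draws followed the counting model that the intervals assume, with independent genes and no variation between cells or libraries. They check the computation only. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and Matplotlib 3.10.9. No raw reads were used here.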

Results

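Single-cell RNA was profiled from whole intervertebral discs of mice that carried a tamoxifen-inducible Cre under Tagln control (Tagln-CreERt2) and a tdTomato reporter in the Rosa26 locus. Tagln encodes transgelin, an actin-binding protein of contractile cells. Tamoxifen was given at day 5 after birth, and discs were taken at day 10 (P10) or at 8 weeks. The series asks whether Tagln-expressing progenitors contribute to the nucleus pulposus (NP), the notochord-derived core of the disc. GEO lists 8 samples, 4 per age, but each age has 1 count matrix with 1 barcode suffix and no map from cells to samples. Each age is therefore 1 library here, age and library cannot be told apart, and no test between ages was possible. The P10 matrix held 7690 barcodes and 143203550 unique molecular identifiers (UMIs), and the 8-week matrix 7597 barcodes and 115097999 UMIs. After filtering, 6999 P10 cells with a median of 18300 UMIs and 6350 cells of 8 weeks with a median of 14689 UMIs were kept. All intervals below are exact 95% intervals (Poisson for levels, Clopper-Pearson for shares, conditional binomial for ratios) and cover counting error only.

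The first comparison asks which cell classes were captured at each age. NP-like cells made up 303 of the 6999 P10 cells (4.33%, interval 3.86 to 4.83%) and 2305 of the 6350 cells of 8 weeks (36.3%, interval 35.1 to 37.5%). They lay in 6 clusters: cluster 14 held 262 of the P10 cells and 82 of the 8-week cells, the cycling cluster 19 held 31 and 130, and clusters 7, 9, 11 and 17 held 10 P10 cells and 2093 cells of 8 weeks. Chondrocyte-like cells made up 60.3% of P10 cells (clusters 0, 2, 3, 12 and 16) and 9.81% of 8-week cells (nearly all in clusters 10 and 25). Hypertrophic chondrocyte-like cells made up 12.7% at both ages (cluster 4 at P10 and cluster 5 at 8 weeks). Tendon fibroblast-like cells, the outer annulus class, made up 11.2% at P10 (cluster 6) and 20.7% at 8 weeks (cluster 1). These 3 classes shared almost no cluster between ages. Cluster 15 was endothelial-like at both ages, with 115 and 129 cells. Smaller classes were mural-like (50 and 30 cells), macrophage-like (66 and 76), neutrophil-like (106 and 27), Schwann-like (122 and 4), osteoblast-like (28 and 93) and connective fibroblast-like (322 and 26). Clusters 8 and 18 passed the marker rule for tendon fibroblasts and for chondrocytes but not the check of their 10 leading genes, and stayed unnamed. They held 0 cells at P10 and 14.4% of cells at 8 weeks. These shares depend on the clustering. Across the alternatives, the chondrocyte-like share at 8 weeks ranged from 0.961% to 33.9%, the hypertrophic chondrocyte-like share from 1.92% to 21.5% and the tendon fibroblast-like share from 0% to 20.8%. At P10 the hypertrophic chondrocyte-like share ranged from 4.23% to 12.7%. Capture by dissociation affects these shares, so they do not measure the composition of the disc.

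The second comparison asks which classes carried the lineage label. The deposited exogenous counts hold 4 named sequences besides the spike-ins. TDT is the tdTomato sequence, and WPRE4 is a 3' element often found in Rosa26 tdTomato transcripts; the labels do not say which reporter allele was used. TDT was sparse, with 218 UMIs in the kept P10 cells and 1433 in those of 8 weeks. In NP-like cells it reached 19.4 UMIs per 1000000 gene UMIs (counts per 1000000, CPM) at P10 (interval 16.2 to 23.001) and 30.03 at 8 weeks (28.4 to 31.7). Mural-like cells had 29.3 (16.7 to 47.5) and 67.3 (39.2 to 107.8), and endothelial-like cells 5.19 (2.76 to 8.87) and 10.0 (6.29 to 15.2). Chondrocyte-like cells had 0.471 and 0.985, the latter 4.30 with each library clustered on its own, and hypertrophic chondrocyte-like cells 0.119 (3 UMIs) and 1.92 (33 UMIs). At full depth a TDT UMI was found in 25.7% of NP-like cells at P10 and 28.5% at 8 weeks. With each cell thinned to 2000 UMIs the shares were 3.74% (1.88 to 6.60%) and 5.53% (4.61 to 6.56%), with 9 and 97 shallower cells left out. TDT was seen in 0 of 106 neutrophil-like cells at P10 and 0 of 27 at 8 weeks, which allows shares of up to 2.83% and 11.1%, and in 1 of 66 and 1 of 76 macrophage-like cells. Median depths were 17519 and 15449 UMIs in NP-like cells, 3168 and 1746 in neutrophil-like cells, and 5528 and 6909.5 in macrophage-like cells. Shares of cells cannot be compared at such unequal depths. Per UMI, macrophage-like cells had 2.19 TDT CPM (0.056 to 12.2) and 1.72 (0.043 to 9.56), lower than NP-like cells. P10 neutrophil-like cells were lower too (0, interval up to 6.78), while the neutrophil-like cells of 8 weeks held too few UMIs for a comparison (0, interval up to 47.5).

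WPRE4 was far more abundant and was taken as a second readout after its values were seen. NP-like cells had 2542 WPRE4 CPM at P10 (interval 2504 to 2580) and 2533 at 8 weeks (2518 to 2548). Mural-like cells had 2783 and 3747, endothelial-like cells 493 and 670, chondrocyte-like cells 32.7 and 62.3, and neutrophil-like cells 62.5 and 116.0. Hypertrophic chondrocyte-like cells had 19.8 and 88.5, a log2 ratio of 2.16 (2.01 to 2.30), and Schwann-like cells 212 at P10, with 4 cells at 8 weeks. In hypertrophic chondrocyte-like cells the NP markers Car3 (26.5 and 235.6 CPM) and Krt8 (7.04 and 37.7) were higher at 8 weeks too, and 10 of their 11 WPRE4-high cells there had at least 10 Car3 UMIs. Both markers were also higher at 8 weeks in other classes. Car3 was 38.2 and 158.2 in chondrocyte-like, 11.5 and 88.6 in tendon fibroblast-like, and 22.1 and 257.7 in neutrophil-like cells. Outside NP-like cells, Car3 was lower at 8 weeks only in connective fibroblast-like and Schwann-like cells (26 and 4 cells there). The 8-week WPRE4 level in chondrocyte-like cells was 260 with each library clustered on its own. At resolution 2 the 8-week mural-like class took in 43 cells that are NP-like in the main clustering, and its levels were 2083 (WPRE4) and 15.1 (TDT). Low WPRE4 counts occurred in every class: at least 1 UMI was present in 24.5% of P10 and 29.6% of 8-week neutrophil-like cells, so a single UMI is read as background. A threshold of 10 UMIs, also set after the values were seen, was passed by 204 of 303 NP-like cells at P10 (67.3%, interval 61.7 to 72.6%) and by 1290 of 2305 at 8 weeks (56.0%, 53.9 to 58.0%). It was passed by 58.0% and 56.7% of mural-like cells, 18.3% and 18.6% of endothelial-like cells, 0.640% and 0.482% of chondrocyte-like cells, and 0 neutrophil-like or macrophage-like cells at either age. The threshold is not adjusted for depth, so the count of 0 in the shallow neutrophil-like cells says little beyond their level per UMI. Per gene UMI, TDT was higher in WPRE4-high cells: NP-like cells above and below the threshold had 26.7 and 0.53 TDT CPM at P10 and 49.6 and 1.07 at 8 weeks. In raw counts, which also rise with depth, among P10 NP-like cells TDT was seen in 0 of 43 cells without WPRE4 and in 48.8% of the 80 cells with at least 80 WPRE4 UMIs. At 8 weeks these shares were 0.583% of 343 cells and 69.0% of 549 cells. At 8 weeks the share of WPRE4-high cells differed between NP-like clusters, among those other than cluster 14 from 44.6% in cluster 19 to 86.6% in cluster 17. It was 34.1% in cluster 14, whose 8-week cells had a median of 1908 UMIs; per UMI its level, 2791 CPM, lay above those of clusters 7 (2327), 11 (2160) and 19 (1652). A cell under the threshold can still carry the recombined reporter.

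**Figure D1:**
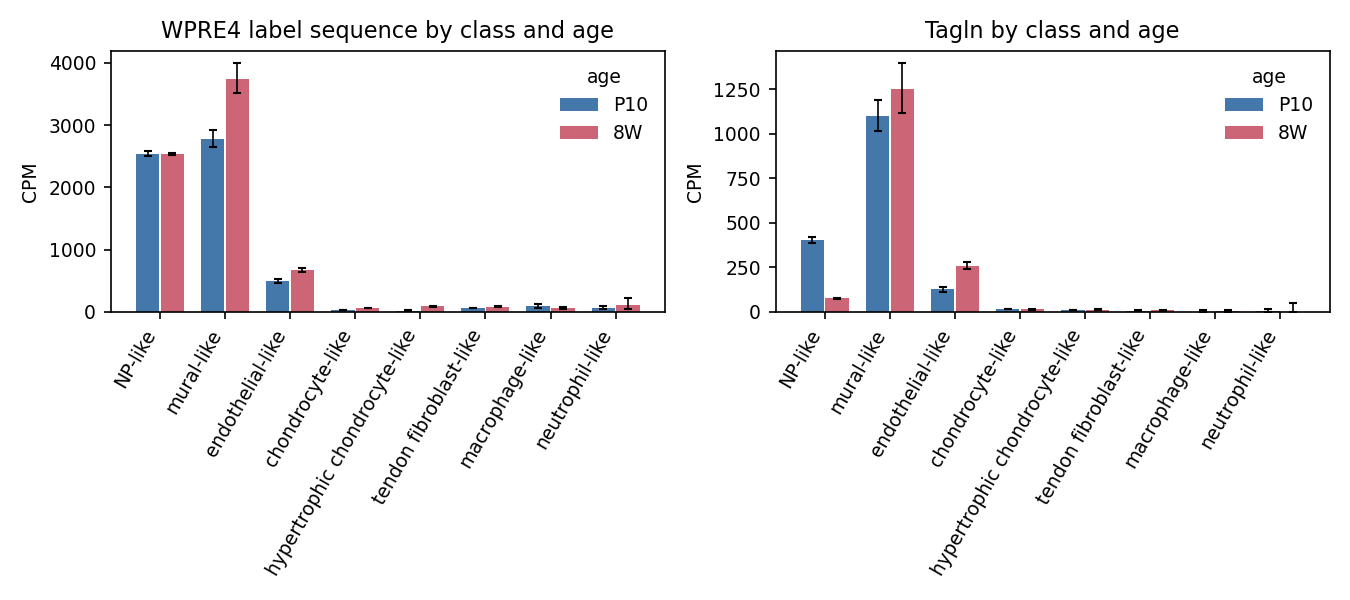
WPRE4 (left) and Tagln (right) in CPM for 8 classes, with P10 and 8 weeks as paired bars and exact 95% Poisson intervals (counting error only) as error bars. WPRE4 is 2542 and 2533 in NP-like cells, while Tagln is 404 at P10 and 77.1 at 8 weeks.

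**Figure D2:**
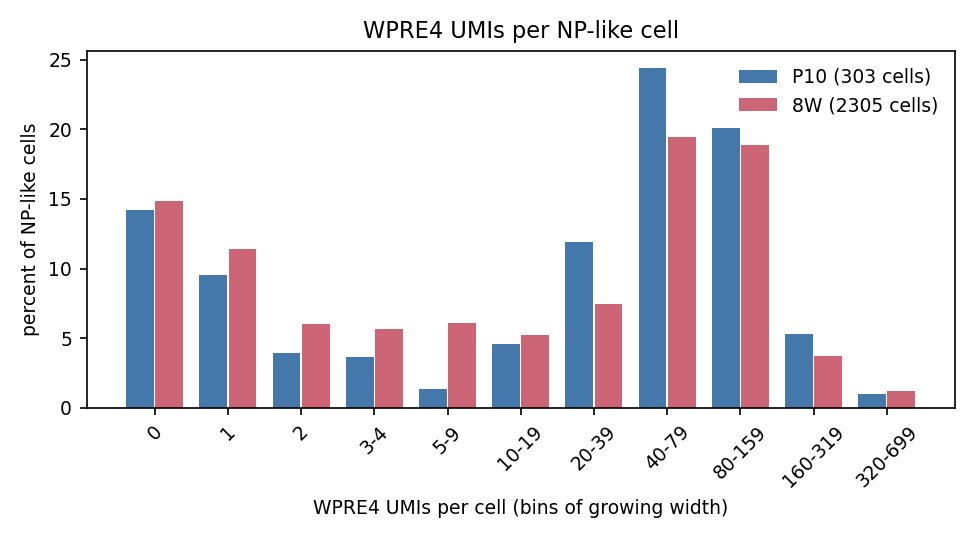
Percent of NP-like cells at each age by WPRE4 UMIs per cell, in bins of growing width. At 8 weeks 14.9% of the cells have 0 UMIs, 11.8% have 3 to 9, 12.7% have 10 to 39 and 23.8% have 80 or more, and 56.0% have at least 10.

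The third comparison asks where Tagln itself was expressed. Tagln (ENSMUSG00000032085, mm10 chromosome 9, 45929619 to 45936058, minus strand) reached 404 CPM in P10 NP-like cells (interval 389 to 419) and 77.1 at 8 weeks (74.5 to 79.7), a log2 ratio of -2.39 (-2.46 to -2.32). It was found in 75.9% and 46.3% of NP-like cells at full depth, and in 38.8% (33.2 to 44.6%) and 12.2% (10.8 to 13.6%) after thinning to 2000 UMIs. Of the neutrophil-like cells, 3 of 106 at P10 and 0 of 27 at 8 weeks had a Tagln UMI. Mural-like cells had 1101 CPM at P10 and 1252 at 8 weeks, a log2 ratio of 0.19 whose interval (-0.02 to 0.38) includes 0. With the 43 cells added at resolution 2, which had 33.99 CPM, the 8-week level was 188.6 and the log2 ratio -2.55. Endothelial-like cells had 126 and 260, a log2 ratio of 1.04 (0.84 to 1.25). The ratio was -0.37 (-0.63 to -0.11) in chondrocyte-like cells, which turned to 0.054 at a coarser clustering. It was 0.24 in both hypertrophic chondrocyte-like and tendon fibroblast-like cells, where the intervals include 0 and scaling to the median gene turns the sign. Within cluster 14, which held most P10 NP-like cells, Tagln was 439.5 at P10 and 40.3 at 8 weeks, but its 8-week cells were shallow (median 1908 UMIs, against 16742 at P10). In cluster 19, with medians of 27806 and 25678.5 UMIs, Tagln was 263 and 52.5.

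The fourth comparison sets NP-like cells of 8 weeks against those of P10 over 11320 genes with at least 100 UMIs in the summed counts. The median gene was 0.35 higher at 8 weeks on the log2 scale; ratios between 0 and 0.35 therefore lie below the median gene. Among NP markers, Car3 had 18306 CPM at 8 weeks and 21130 at P10 (log2 ratio -0.21), Krt8 2829 and 3609 (-0.35), Krt19 1513 and 2447 (-0.69), and Krt18 had a log2 ratio of -0.26, which was 0.39 within cluster 14. T (brachyury) had a log2 ratio of 0.16, a direction that turned under each of the 3 other scalings. Cdh2 was higher at 8 weeks (log2 ratio 1.52), Slc2a1 lower (-0.32) and Foxa2 lower (-1.48, interval -2.01 to -0.93). Without the P10 cells carrying markers of another class Foxa2 was at -0.31 with an interval that includes 0, as does the interval of Foxa1 with all cells. Shh had 54 UMIs at 8 weeks and 7 at P10, under the minimum, and Noto had 0 at both ages.

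The actin gene Acta2 (ENSMUSG00000035783, chromosome 19) was lower at 8 weeks along with Tagln, at 392 against 1562 CPM (log2 ratio -1.99, interval -2.03 to -1.96). The list of contractile genes and serum response factor targets had a median log2 ratio of -1.05 over 13 genes, lower than all 10000 expression-matched random lists; Tpm1 had -1.05 and Csrp1 -1.11. The cell cycle list had a median of -0.74, also lower than all random lists. Genes of a random list were drawn independently, while members of 1 list can vary together. Percentiles here and below are therefore ranks and no test between ages. The cell cycle median was -3.91 with each library clustered on its own and -0.24 in cluster 14. Mki67 was seen in 19.8% of P10 and 8.50% of 8-week NP-like cells. The glycolysis and hypoxia list was at -0.52 (percentile 0.10). Basement membrane genes were at -0.61 (percentile 0.20), with 3 of 6 members higher and 3 lower, and their median was 1.10 after thinning. The notochord and hedgehog list was at 0.41 (percentile 74.4), with Sox9 at 1.17, and the epithelial-type keratin and junction list at -0.19 (percentile 7.60).

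The matrix lists depended on few cells. At P10, 26 of 303 NP-like cells (8.58%) and at 8 weeks 75 of 2305 (3.25%) carried at least 10 UMIs of markers of another class, a definition set after the values were seen. It is not adjusted for depth. These cells had a median of 33002 UMIs at P10, against 16684 in the others, and 56265 against 15107 at 8 weeks. Their median doublet scores were 0.285 against 0.026 at P10 and 0.059 against 0.031 at 8 weeks. Leaving them out therefore also removes deep cells. Without these cells the fibrillar and fibrous matrix list had a median of -0.085 (percentile 20.1) in place of -0.72 (percentile 0.01), and the cartilage and NP matrix list 0.64 (percentile 99.2) in place of -0.02 (percentile 31.2). With only the 26 P10 cells left out the 2 medians were 0.26 and 0.78, and with only the 75 cells of 8 weeks left out -0.85 and -0.11. Col2a1 had a log2 ratio of -1.56 with all cells and -0.60 without them, and Sparc -0.72 and -0.20. Col2a1 was also found in P10 blood cells, at 29840 CPM in neutrophil-like and 6834 in macrophage-like cells, against 6398 in NP-like cells. Acan (0.79 and 0.77), Fmod (0.71 and 0.77) and Fn1 (0.95 and 0.91) differed little. The list of matrix proteases and inhibitors had -0.15 and 0.40. The contractile, cell cycle and glycolysis lists kept their side without these cells, at -1.11, -0.80 and -0.57.

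Medians of the other lists, with percentiles, were 0.05 for oxidative phosphorylation (54.5), 0.12 for progenitor markers (21.6), 0.39 for TGF-beta and BMP (81.6), 0.65 for YAP and TEAD targets (86.6), 0.23 for immediate early and heat shock genes (93.2), -0.14 for endoplasmic reticulum stress (6.28), 0.29 for interferon response (48.2) and 0.32 for aging and cell cycle arrest (60.5). Of these 8 medians, those for YAP and TEAD targets and for endoplasmic reticulum stress kept their sign under all alternatives run, and the other 6 did not. The ambient blood list stood at 6.31, but 4 cells held 98.4% of the hemoglobin UMIs of NP-like cells at 8 weeks.

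**Figure D3:**
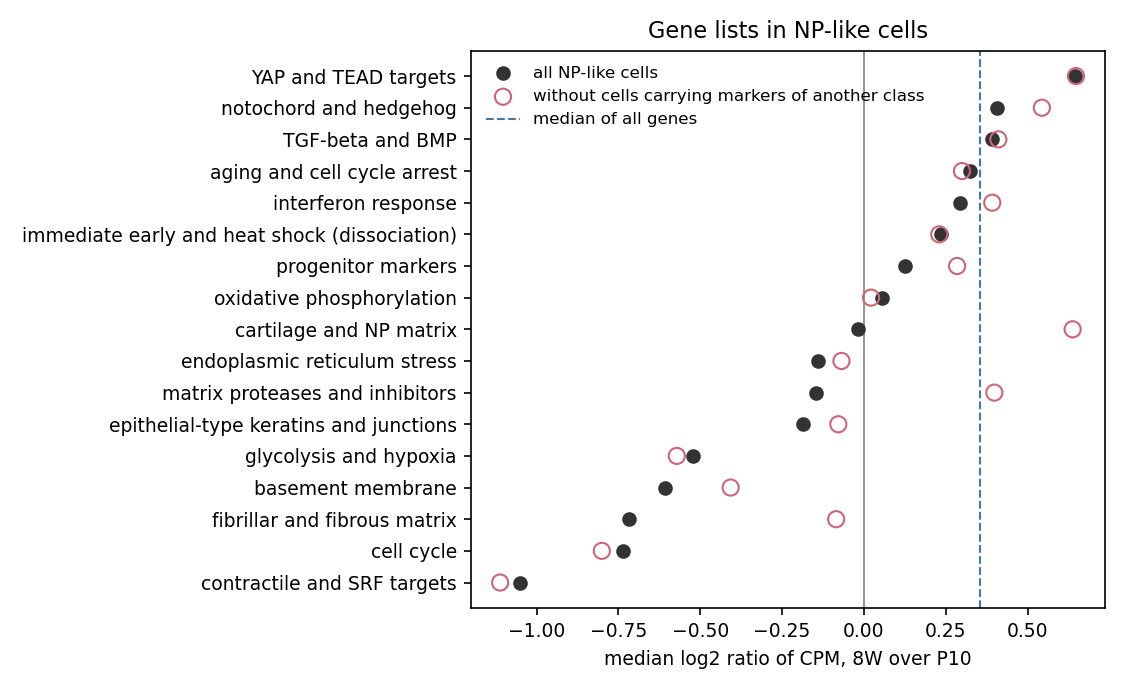
Median log2 ratio of CPM (8 weeks over P10) for 17 gene lists in NP-like cells, with all cells (filled points) and without cells that carry markers of another class (open points); the dashed line is the median of all genes. The fibrillar list lies at -0.72 with all cells and at -0.085 without those cells, while the contractile list lies at -1.05 and -1.11.

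By the fixed rule, the genes highest at 8 weeks in NP-like cells were Nrn1, H2-T23, Sema4a, Krt78, Ibsp, Bsx, Csf2 and Sorl1. Nrn1 had 6090 UMIs at 8 weeks and 8 at P10, the latter in 2 cells (log2 ratio 6.87, interval 5.89 to 8.09). Across the alternatives this log2 ratio lay between 4.53 and 7.29. H2-T23, Krt78 and Bsx had 0 UMIs at P10 and were at least 33.6-fold, 15.2-fold and 14.1-fold higher at 8 weeks against a floor of 3 counts over the group. Per cell, H2-T23, Sema4a and Sorl1 had less than 2 times the level in blood cells, which can also hold their own transcripts of these genes. Csf2 came from 115 of the 2305 cells. The lowest were H19, Dlk1, Tdrd12, Pgam2, Epyc, Cdkn1c, Fabp4 and Mmp2, with log2 ratios from -9.40 for H19 to -4.57 for Cdkn1c. Ibsp had 4.65, which was 0.74 with each library clustered on its own. All 16 kept their direction without the cells carrying markers of another class, but H19 was then at -6.40, Dlk1 at -4.70, Epyc at -3.18, Mmp2 at -2.70, Cdkn1c at -2.51 and Fabp4 at -1.88.

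The fifth comparison repeats the contrast of ages in the other classes with at least 100 cells at both ages, to show which differences other cells share. The median gene was 0.39 higher at 8 weeks in chondrocyte-like, 0.44 in hypertrophic chondrocyte-like, 0.39 in tendon fibroblast-like and 0.17 in endothelial-like cells. The contractile list was lower at 8 weeks in chondrocyte-like (median -1.04, and -0.23 after thinning) and tendon fibroblast-like cells (-1.32). It was at -0.13 in both hypertrophic chondrocyte-like and endothelial-like cells, which became 0.09 at a finer clustering and 0.40 after thinning. Acta2 had log2 ratios of -3.32, -0.90, -3.64 and -0.29 in the same order as above, the last of which became 0.41 after thinning. With each library clustered on its own the first 2 were -0.98 and -0.094. The glycolysis and hypoxia list was lower in all 4, with medians of -1.03, -1.31, -0.57 and -0.50. Immediate early and heat shock genes were higher at 8 weeks in all 4 classes, with medians of 1.40, 2.33, 1.91 and 0.61 (percentiles from 99.77 to 100), against 0.23 in NP-like cells, where 6 of 12 members were higher and the median was -0.09 with TMM and -0.85 in cluster 14. The genes named by the rule included Serpina1a, with 0 UMIs at P10 and at least 1715-fold higher at 8 weeks in chondrocyte-like cells, and Dlk1, lower by a log2 ratio of -9.20 in chondrocyte-like and -6.29 in hypertrophic chondrocyte-like cells. The others in chondrocyte-like cells were Serpina1d, Adra2c and Gjb6 (higher) and Mfap4, Fbn2 and Hist1h2br (lower), and in hypertrophic chondrocyte-like cells Serpina1a, Serpina1d, Gjb6 and Serpina1b (higher) and Npy, Dpysl4 and C1qtnf3 (lower). In tendon fibroblast-like cells Saa1, Myoc, Saa2 and Cytl1 were higher and Mfap4 (-10.72), Cthrc1, Fbn2 and Ggt1 lower. This class was cluster 6 at P10, with 7 of 8 tendon markers at the 2-fold level, and cluster 1 at 8 weeks, with 4 of 8. Cluster 8 of 8 weeks, with 7 of 8, stayed unnamed and was left out. The ratios of this class, those of Acta2 and the contractile list included, may therefore compare different cells. Of the 623 chondrocyte-like cells of 8 weeks, 562 lay in cluster 10, with 0 cells at P10 and 1 of 11 chondrocyte markers at the 2-fold level. Hypertrophic chondrocyte-like cells were cluster 4 at P10 and nearly all cluster 5 at 8 weeks. The ratios of both chondrocyte classes, Serpina1a and Dlk1 included, may compare different cells too. In endothelial-like cells the UMIs of Ccl21a and Mmp13 came from 1 cell each. Of the others there, Angptl7 and Cilp2 were higher, and the cartilage genes Col9a1, Epyc, Cnmd and Col9a3 were lower, with 91.8% to 98.5% of their P10 UMIs in the 10% of cells with the most.

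The sixth comparison sets NP-like cells with a TDT UMI against those without, within each age. Among NP-like cells with at least 80 WPRE4 UMIs, TDT was seen in 48.8% at P10 and 69.0% at 8 weeks. Cells without a TDT UMI can therefore still carry the label. The split is by detection of TDT, in cells of unequal depth, and does not separate labelled from unlabelled cells. At P10, 78 cells with TDT (median 22429 UMIs) were set against 225 without (16111), and at 8 weeks 658 (19252.5) against 1647 (13759). Tagln was higher in cells with TDT at P10 (516.7 against 344.5 CPM, log2 ratio 0.58, interval 0.47 to 0.69). At 8 weeks the log2 ratio was 0.14 (0.04 to 0.24), and it was -0.0094 after thinning, so no direction is stated. Acta2 had log2 ratios of 0.20 and 0.16. The contractile list had medians of 0.14 and -0.05, and 0.03 and -0.07 without cells carrying markers of another class. The cartilage list had -1.04 at P10 with all cells and -0.01 without those cells. Immediate early genes had 0.40 at P10 and -0.19 at 8 weeks.

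Split at 10 WPRE4 UMIs, which balances depth better at 8 weeks (medians 15444 and 15474 UMIs), the contrast held 204 against 99 cells at P10 and 1290 against 1015 at 8 weeks. Tagln was higher in WPRE4-high cells at both ages, with log2 ratios of 1.25 (1.09 to 1.41) at P10 and 0.22 (0.11 to 0.32) at 8 weeks, as was Acta2 (0.72 and 0.34). The contractile list had a median of 0.34 at P10, higher than all random lists, and -0.05 at 8 weeks (percentile 25.1). At 8 weeks 15 of 17 cell cycle genes were lower in WPRE4-high cells with an interval clear of 0. The median was -0.72, which was -0.14 with each library clustered on its own, and Mki67 was seen in 7.44% of WPRE4-high and 9.85% of other cells. At P10 the cell cycle median was -0.18. Immediate early genes had -0.16 at P10, and -0.26 at 8 weeks. Of the 12 members, 6 were lower and 1 higher with an interval clear of 0 at P10, and 12 were lower at 8 weeks. These member counts, like those of the cell cycle list, rest on pooled cells of 1 library per age. The share of all genes with such an interval was not computed.

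The last comparison sets NP-like cells with a Tagln UMI against those without. At P10 it held 230 cells (median 18263 UMIs) against 73 (13829), and at 8 weeks 1067 (18798) against 1238 (12620.5). Acta2 was higher in cells with Tagln, with log2 ratios of 1.60 (1.49 to 1.71) at P10 and 0.68 (0.63 to 0.73) at 8 weeks. The contractile list, Tagln left out, had medians of 0.48, higher than all random lists, and 0.08 (percentile 98.3). Immediate early genes were also higher (0.68 and 0.21), and the cell cycle list had -0.48 and -0.25, the latter of which turned to 0.39 with each library clustered on its own. The cartilage list had -0.40 at P10 and 0.01 at 8 weeks.

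In these 6 splits the rule named 96 genes, of which 73 kept their direction, with an interval clear of 0, without cells carrying markers of another class; the genes given here were chosen among those after their values were seen. With TDT at P10, Egr1 (0.76), Tmem41b and Sln were higher; with TDT at 8 weeks, Dlx5 (0.78) and Peg10 were higher and Krtdap and Dab1 lower. In WPRE4-high cells, Gldn was higher (2.46) and Ctgf (-1.24), Ube2c and Mfge8 lower at P10, and Dlx5 (1.52), Fam181b, Wnt16 and Ndnf were higher and Penk (-1.88) and Kif2c lower at 8 weeks. The mix of clusters was not held constant in this split. At 8 weeks the WPRE4-high share was 86.6% in cluster 17, whose 10 leading genes include Wnt16 and Ndnf, and 44.6% in the cycling cluster 19. In cells with Tagln, Krt80, Myl9, Rnd3 and Kctd12 were higher and Mfge8 (-2.24) lower at P10, and Mast1 and Urah higher and Dab1 (-1.27) lower at 8 weeks.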

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

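All tests of explanations in this part were chosen only after the results they address had been seen.

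Tagln differed between ages in opposite directions in different classes: its log2 ratio (8 weeks over P10) was -2.39 in NP-like cells and -0.37 in chondrocyte-like cells, but 1.04 in endothelial-like cells. With 1 library per age, the difference between classes was not tested. Immediate early and heat shock genes also went opposite ways: in NP-like cells with a TDT UMI against those without, the list median was 0.40 at P10 and -0.19 at 8 weeks, a difference that was not tested either. CRE transcripts, which enter no comparison, appeared with 7 UMIs at P10 and 6 at 8 weeks, above the 3 counts that a count of 0 allows. At P10 they lay in 4 NP-like cells, all with Tagln, in 2 chondrocyte-like cells and in 1 hypertrophic chondrocyte-like cell. At 8 weeks 4 lay in NP-like cells, 2 of which had Tagln. Tagln was found in 75.9% of all NP-like cells at P10 and 46.3% at 8 weeks, so these few cells show no link between CRE and Tagln.

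The lower Tagln level in 8-week NP-like cells was weighed against technical causes. Without cells carrying markers of another class the log2 ratio was -2.48 (-2.56 to -2.40), so the cells left out do not account for the lower level. Of the 26 P10 cells left out, 20 carried chondrocyte markers and 1 mural markers. Mural-like cells were the only P10 class with more Tagln than NP-like cells (1101 against 404 CPM). Leaving these cells out could therefore hardly raise the ratio, and mixtures under 10 marker UMIs are not covered. Within cluster 19, of similar depth at both ages, it was -2.32 (-2.58 to -2.07), so Tagln was lower within that cluster too. Cluster 19 was set apart by cycling and can thus hold other NP-like states at each age. Its Nrn1 level was 0 CPM at P10 and 71.4 at 8 weeks. Nrn1 was named from the contrast of ages itself, so this difference cannot tell such states from age. The clusters with most 8-week NP-like cells held 10 P10 cells, so another mix of NP-like states cannot be told apart from age. Within cluster 14 the Tagln log2 ratio was -3.45 (-4.45 to -2.61), but the 82 cells of 8 weeks there had a median of 1908 UMIs, against 16742 at P10. In mural-like cells it was 0.19 (-0.02 to 0.38), and in endothelial-like cells 1.04 (0.84 to 1.25), from 0.88 to 1.52 under alternatives, which argues against a difference between the libraries that acts on Tagln in all cells. The mural-like value was -2.55 at resolution 2, where 43 cells that are NP-like in the main clustering joined the class; the 30 cells mural-like in both kept 0.19. Acta2 and the contractile list, however, were also lower in chondrocyte-like (list median -1.04, and -0.23 after thinning) and tendon fibroblast-like cells. Both classes shared almost no cluster between ages. Handling that acted on NP-like cells of 1 age cannot be told apart from age with 1 library per age. Age itself stays open as a biological explanation and was untested.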

How the results depend on the processing

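The alternatives on doublet score, WPRE4, cells with markers of another class, the cycling cluster, cluster 14 alone and free RNA, and the changes of clustering in classes other than NP-like cells and in the Tagln splits, were chosen only after the data were seen. No paired analysis was possible because cells could not be assigned to animals, and for the same reason no sample could be left out. Of 2396 log2 values under alternatives, 2296 kept their direction, 100 did not, and 11 of these turned a value whose interval (for a list, that of the median over its members) had excluded 0. Among the others are the basement membrane (1.10, thinned) and fibrillar medians. Over all lists 11 of 2707 values turned such a result, and over all genes named by the rule 273 of 12416, so genes without a value in the text turned more often than those given. Of the 2396 values, 193, for 74 of 164 results, lay over 1.5-fold from the reported one. The Tagln log2 ratio in NP-like cells lay between -3.45 and -2.27, and the contractile median between -1.40 and -1.03. Shares of other classes at 8 weeks were unstable, from 0.961% to 33.9% (chondrocyte-like), 1.92% to 21.5% (hypertrophic chondrocyte-like), 0% to 20.8% (tendon fibroblast-like) and 5.95% to 23.2% (unnamed). So were 8-week label levels: in mural-like cells Tagln was 188.6, TDT 15.1 and WPRE4 2083 CPM at resolution 2, where 43 NP-like cells joined the class, and in chondrocyte-like cells WPRE4 was 260 and TDT 4.30 with libraries apart.

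Many values left their interval, among them 368 log2 ratios of single genes; Acta2 in NP-like cells lay between -2.34 and -1.72. For NP-like cells, the levels and shares that did so were these. WPRE4 CPM at 8 weeks was 2562 at resolution 2, 2477 with doublets kept, 2636 with libraries clustered apart and 2603 without cells carrying other markers; at P10 it was 2593 with the score limit, 2486 with libraries apart and 2678 without those cells. Tagln CPM at P10 was 419.7 with the score limit and 438.7 without those cells, and 80.97 at 8 weeks with libraries apart; TDT at 8 weeks was 32.0 without those cells. The NP-like share at 8 weeks was 33.5% with libraries apart. The WPRE4-high share at 8 weeks was 53.0% with the looser and 58.3% with the stricter filter, and 62.1% and 50.7% at 5 and 20 UMIs. The TDT share was 25.7% (P10) and 28.5% (8 weeks) without thinning, 8.25% and 11.5% without thinning and with at least 2 UMIs, which changes 2 choices, and 2.82% and 8.59% at 8 weeks when thinned to 1000 and 3000 UMIs.

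The Tagln log2 ratio was -2.27 with libraries apart, -2.72 with TMM, -2.74 with the median of ratios, -2.55 with the reduced total, -2.49 thinned, -2.47 without the cycling cluster, -3.45 in cluster 14, -2.46 without cells carrying chondrocyte markers and -2.48 without those of any class (-2.51 with only the P10 ones left out). In the TDT split, thinning gave Tagln 0.47 at P10 and turned it to -0.0094 at 8 weeks. Immediate early genes in chondrocyte-like cells were at 2.08 at resolution 0.5, and the cell cycle median in the 8-week WPRE4 split at -0.14 with libraries apart.

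Other values turned: Tagln in chondrocyte-like cells (0.054, resolution 0.5); ambient blood (-4.71, looser filter); cell cycle in the 8-week Tagln split (0.39, libraries apart) and in the P10 TDT split (0.32 with per-cell means, 0.13 without cells carrying other markers); T in NP-like cells (-0.16 with TMM, -0.19 with the median of ratios, -0.00058 with the reduced total), since these scalings lower every ratio by 0.33, 0.35 and 0.16; Acta2 in endothelial-like cells (0.41, thinned); and Krt18 in cluster 14 (0.39). For all values of this part but those with a cause given, the cause was not tested. Depth limits TDT, with 131 UMIs in P10 NP-like cells, and CRE, with 4.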

Other observations

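The tests of explanations in this part were chosen only after the results they address had been seen, and each is a hypothesis tested on the data that gave rise to it.

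The lower median of the fibrillar matrix list in 8-week NP-like cells (-0.72) may come from P10 droplets that captured an NP-like cell with a cell of another class. Without cells carrying markers of other classes, none of them on the list, the median was -0.085, with members from -1.07 to 0.91, and -0.14 with the gene minimum applied anew; with the filter as first set, on chondrocyte markers alone, it was -0.16. With only the P10 cells left out it was 0.26, and with only those of 8 weeks left out -0.85. It was also 0.02 at a doublet score under 0.25, 0.12 after thinning and 0.26 with the 8-week doublets kept, so its side depends on the cells and depth kept. Chondrocyte markers were found in 8.72% of P10 blood cells (interval 4.96 to 14.0%) and 6.60% of P10 NP-like cells (4.08 to 10.0%), and the 26 cells held 16.4% of the P10 NP-like UMIs but a median of 40.4% of those of the list's genes. Free RNA in the droplets stays open, as does age, which was not tested: the median after subtraction was 0.17 with the background as first set, which would favour it, and -0.72 with the background redefined after that result was seen.

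WPRE4 was high in 45 of the 244 endothelial-like cells of both ages. Capture together with NP-like cells cannot be the whole cause, since 13.3% of the 45 (5.05 to 26.8%) had at least 10 Car3 UMIs. Mural markers reached 10 UMIs in 68.9% of the 45 (53.4 to 81.8%) and in 11.1% of the other 199 (7.06 to 16.3%), which is consistent with capture together with mural-like cells. In the WPRE4-high and other cells Pecam1 was 1298 and 1352 CPM and Cdh5 674 and 768, while mural-like cells had 0 of both. At P10 neither was lower in the WPRE4-high cells (Pecam1 1101 against 1040, Cdh5 677 against 668). At 8 weeks both were lower (Pecam1 1554 against 1686, Cdh5 670 against 875). These values do not decide whether mural RNA diluted the endothelial markers. Capture with mural-like cells is therefore not settled. Labelled endothelial cells stay open for all 45 cells, including the 14 without mural markers, and no biological explanation was tested.

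EGFP and the 92 ERCC sequences had 0 UMIs at both ages. Of all WPRE4 UMIs, 94.8% at P10 and 91.6% at 8 weeks lay in barcodes called as cells by the authors. The lowest UMI total of a deposited barcode was 500 at both ages.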
